A study of Arabidopsis thaliana x Arabidopsis lyrata and Arabidopsis thaliana x Arabidopsis halleri with 18 samples.

How the data were processed

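Total RNA came from the whole aerial part of 1 F1 hybrid plant per library, extracted with TRIzol and prepared with the TruSeq RNA v2 kit, per the labels' protocols. Plants were stratified for 5 days and grown for 4 weeks at 22 °C with 16 h of light and 8 h of dark, per the labels. The 18 libraries fell into 6 groups of 3 plants by the hybrid and treatment in their labels. Standard samples were described as leaf samples, and replicates were prepared at intervals of a week, per the labels' protocols, which do not say that a replicate number marks a week.

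Each deposited file gave a score per gene for the *A. thaliana* allele and for a second allele, per the file headers. From the values, the deposited score is a read number scaled by 1 factor per library to a near-equal total, rounded to a whole number, with 1 added. TopHat2, SAMtools, DESeq2 and the build TAIR10 are named without versions or roles, per the submitters' processing notes. How reads were assigned to alleles is not given in the sources used here. Because the deposited values are scaled, the exact depth of most libraries is unknown. In 5 libraries, all of dehydrated plants, whole numbers were missing at regular steps, which gave implied totals between 930583 and 1430056 reads. No number was missing in the other libraries, so these were not visibly scaled up and held about their deposited total or more. Lower depth thus went with dehydration in those 5 libraries, a limit on every dehydration comparison. Of 16419 genes, 16404 were matched to the TAIR10.1 annotation, which was used for symbols and coordinates, and 15 were not. No 2 libraries were identical, and the lowest correlation between libraries of a group was 0.704.

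A count test had been planned, and limma on a log2 scale replaced it because the deposited values are not counts. For total expression the alleles were summed, the 1 added to each was taken off, and the sum was scaled by TMM factors (trim of 30% of log ratios and 5% of means, computed in R). The test used log2 of the scaled sum plus 2, so a fold change is on that scale and understates the change of low genes. Genes with a value of at least 10 in at least 3 libraries were tested. All 18 libraries entered 1 fit with a mean per group, in R 4.3.3 with limma 3.58.1 (eBayes with trend and robust) and jsonlite 2.0.0. The allele comparison used log2 of the second allele over the thaliana allele per plant, as deposited, for genes with a mean of at least 10 per plant, fitted per hybrid. The 1 added to each allele was kept there, so the ratio of a low gene is pulled toward equal alleles. P values were 2-sided and adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p below 0.05. Treatments were compared with standard plants within a hybrid, and the hybrids with each other by an interaction term and under standard conditions.

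The 17 gene lists held 336 genes, of which 242 were in the files. They were early cold regulators, cold-regulated targets of CBF, abscisic acid and dehydration, jasmonate, rapid touch, wound and defence, circadian clock, heat shock, photosynthesis, darkness and sugar starvation, flavonoid synthesis, auxin and growth, aquaporins, glucosinolates, metal homeostasis, root markers, floral organ genes and reference genes. RD29A is on 2 lists. Lists were tested with camera (preset correlation 0.01), again with a correlation estimated from the data and with fry, adjusted over the lists of a comparison, and Fisher's exact test compared allele directions. Named genes were chosen by a rule. For each comparison it took the 5 largest rises and 5 largest falls among called genes with a mean of at least 50 in the higher group (for allele ratios, per plant over both alleles) and no overlap between replicates (for allele ratios, every plant on the same side). It also took up to 4 members of each list with the smallest p. For interactions the 5 largest in each direction were taken without the overlap condition. Chance gives no overlap in 10% of orderings of 3 against 3. Groups, comparisons, lists, the rule and the first set of other settings were fixed before the data were examined.

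That first set of other settings was relative log expression scaling, no filter, a fit of only the groups compared, a replicate block, each library left out in turn, a mean of at least 50, centring of the allele ratio, and 0.5 added to each allele. Settings chosen after the data were seen were the scaling as deposited, 10 added before log2, library weights, and leaving out the 3 libraries that stood apart. Random draws used seed 1. The total test was tested on simulated data in the design of the cold comparison of lyrata-labelled plants. It recovered 36 of 100 genes changed 4-fold and 97 of 100 changed 16-fold over 12766 genes, with 4 false calls among 137. For the cold change of the allele ratio in lyrata-labelled plants it recovered 78 of 100 and 100 of 100 over 11692 genes, with 12 false calls among 190. Simulated genes were independent and shared 1 spread, and no simulated library stood apart. The shares of false calls are therefore not error rates of the real calls.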

Results

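RNA was sequenced from aerial tissue of F1 hybrids between *Arabidopsis thaliana* (Col-0) and 1 of its perennial relatives. The labels name *Arabidopsis lyrata* (accession MN47) as the other parent of 9 plants and *Arabidopsis halleri* as that of the other 9. In an F1 hybrid both parental alleles sit in the same nucleus, so reads assigned to each allele compare the parents' cis-regulation under shared conditions. Plants were 4 weeks old and were kept under standard conditions at 22 °C, exposed to 4 °C for 1 hour, or dehydrated for 1 hour at 22 °C. Both stress treatments were given in dim light. Each of the 6 groups held 3 plants, and each library came from 1 plant, so the spread between replicates is a spread between plants. The labels give the rosette as the source and the whole aerial part as the material extracted, but call the standard samples leaf samples. Whether standard and treated plants were of the same tissue is therefore open in each treatment comparison. The labels also do not state the time of day of sampling. A difference in clock time between standard and treated plants is thus open as well, for every gene that changes over the day. By its title, the series asks how cis-regulation of stress-responsive genes diverged in this genus.

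Each library gave a normalised read count for the *A. thaliana* allele and for the other allele of 16419 genes. The deposited totals lay between 1524104 and 1531268 per library, because the values had been scaled to a near-equal total. Between 9493 and 11874 genes per library reached a summed value of 10. The 10 most abundant genes took 2.29% to 12.1% of a library. The *A. thaliana* allele took between 49.12% and 51.09% of the total in all libraries except lyrata-labelled dehydration replicate 2, where it took 61.27%. The median log2 ratio of non-thaliana to thaliana allele was -0.709 in that plant and between -0.064 and 0.08 in the other 8 lyrata-labelled plants.

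The names of the alleles in the files and the labels of the plants did not match. In all 9 lyrata-labelled files the second allele was headed as *A. halleri*, and in all 9 halleri-labelled files it was headed as *A. lyrata*. The plants are therefore called lyrata-labelled and halleri-labelled throughout, and the second allele is called the non-thaliana allele. Which species a difference between the hybrids belongs to depends on which of the names is right. Lyrata-labelled standard replicate 1 (TMM factor 0.7724), lyrata-labelled dehydration replicate 2 (the share of 61.27%) and halleri-labelled cold replicate 1 (TMM factor 1.172) stood apart. Each count was also taken without these 3 libraries, a choice made after the data were seen. Halleri-labelled standard replicate 1 stayed in, with a TMM factor of 0.8646 and the lowest mean correlation with its own group (0.72). So did lyrata-labelled cold replicate 2, with a TMM factor of 1.136. Counts without either are among those with each library left out in turn. Members of near-identical families such as the aquaporins, the light-harvesting genes and the CBF genes are uncertain where the authors' counting could split their reads, and the kit did not mark strand, so overlapping and antisense genes cannot be told apart.

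**Figure D1:**
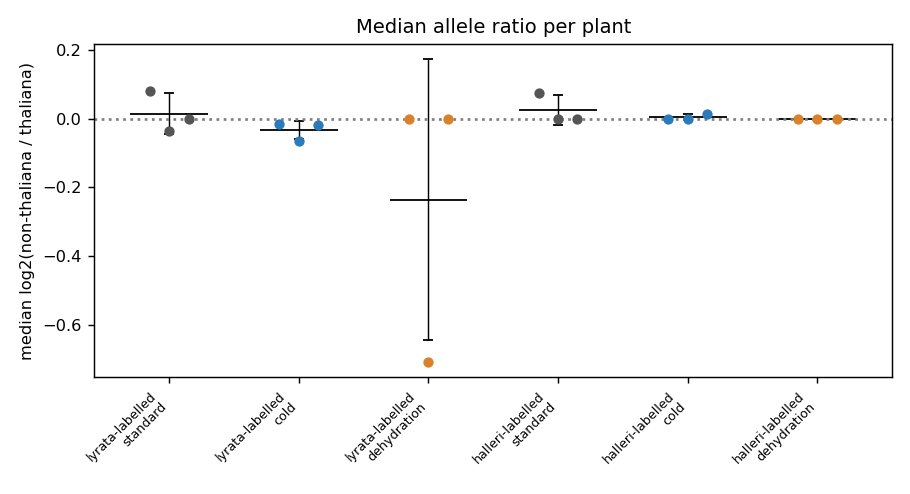
Median log2 ratio of non-thaliana to thaliana allele over genes for each plant (points), with the mean (line) and SD (bar) of each group of 3 plants. Lyrata-labelled dehydration replicate 2 lies at -0.709, and the other 17 plants lie between -0.064 and 0.08.

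In lyrata-labelled plants, 1 hour of cold was compared with standard conditions. Genes of the circadian clock were among the largest changes. PRR5, an evening-phased repressor of the clock (chromosome 5, 8356204 to 8358546, TAIR10.1), rose from 7.69 ± 1.06 to 229 ± 58 (SD, n = 3), a log2 fold change of 4.55 ± 0.56 (SE). LUX, a component of the evening complex, rose by 4.03 ± 0.61 on the log2 scale, and ELF4 of the same complex rose by 2.99 ± 0.6. LHY, a morning-phased clock factor, fell by 3.65 ± 0.7, from 198 ± 58.8 to 15.4 ± 8.83. The other large rises included FAP1 (4.88 ± 1.06), AT5G57760 (4.82 ± 0.69), the invertase A/N-InvC (4.49 ± 0.72) and ABCF2 (4.41 ± 0.63). Other large falls, among called genes with a mean of at least 50 in the higher group and no overlap between replicates, were AT2G25150 (-5.11 ± 0.83), AKN2 (-4.94), CDEF1 (-4.42), GSTF12 (-3.88) and SR34a (-3.65).

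By list, 4 of the 23 clock genes rose and 1 fell in the cold lyrata-labelled plants, and 8 rose and 1 fell when adjusted over the list alone. None of the 13 early cold regulators passed over all genes, and 7 rose when adjusted over the list alone; RAV1 was at 2.2 ± 0.54 (adjusted p = 0.058), and CBF2, an activator of cold-regulated genes, was listed at 0 in all 3 standard plants and at 15.1 ± 8.41 in cold (adjusted p = 0.092). All 13 had a positive fold change, and camera called the list higher (adjusted p = 2.8e-05; adjusted p = 0.14 with an estimated correlation). Camera also called the clock list higher (adjusted p = 0.0053; adjusted p = 0.14 with an estimated correlation). None of 25 nuclear photosynthesis genes passed, 24 had a negative fold change with a list median of -1.4, and 5 fell when adjusted over the list alone. Camera called that list lower (adjusted p = 8e-06; adjusted p = 0.14 with an estimated correlation). None of 12 aquaporins passed, and 4 fell when adjusted over the list alone; the lowest p belonged to PIP2;1 (-1.95 ± 0.51, adjusted p = 0.067). Camera called the aquaporins lower (adjusted p = 3.9e-05; adjusted p = 0.14 with an estimated correlation).

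Of 16 genes induced by darkness or sugar starvation, TPS11 rose in the cold lyrata-labelled plants (3.16 ± 0.65), and 2 rose when adjusted over the list alone. Camera called that list higher (adjusted p = 0.00077; adjusted p = 0.26 with an estimated correlation). Of 9 flavonoid genes, DFR fell (-3.68 ± 0.74), and 2 fell when adjusted over the list alone. Camera called them lower (adjusted p = 0.015; adjusted p = 0.29 with an estimated correlation). No jasmonate gene passed (1 of 12 rose when adjusted over the list alone), and neither did any of 15 touch, wound and defence genes (5 rose when adjusted over the list alone). Camera called the jasmonate list higher (adjusted p = 0.0053; adjusted p = 0.29 with an estimated correlation) and the touch, wound and defence list higher (adjusted p = 0.0018; adjusted p = 0.29 with an estimated correlation). No metal gene of 24 passed, nor any when adjusted over the list alone, and camera called the list lower (adjusted p = 0.046; adjusted p = 0.14 with an estimated correlation). The small heat shock gene HSP17.6II was listed at 0 in all 3 standard plants and at 59.6 ± 55.5 in cold (adjusted p = 0.018), as 1 of 9 heat shock genes that passed; 2 rose and 1 fell when adjusted over the list alone. BCAT4, of aliphatic glucosinolate synthesis, fell by 2.17 ± 0.41, as 1 of 11 glucosinolate genes; 1 rose and 2 fell when adjusted over the list alone.

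In all, limma called 115 of 13058 genes in the cold lyrata-labelled plants (83 higher, 32 lower), and 1980 had an unadjusted p under 0.05 where chance gives 653. With the scaling as deposited it called 139 (120 higher, 19 lower), as that scaling moved the median of all genes to 0.23 on the log2 scale. With 10 added before log2 it called 83 higher and 64 lower. The count was 23, 22 and 53 without cold replicates 1, 2 and 3, and 75 and 71 without standard replicates 1 and 2. It was 12 when only the 6 libraries compared were fitted, 520 with library weights and 60 without the 3 libraries that stood apart. Of the 17 called genes named by the rule, AT5G57760, PRR5, A/N-InvC, ABCF2, AT2G25150 and LUX kept their calls without any 1 library. The other 11 lost them without at least 1 of those 5 libraries, with an adjusted p of up to 0.14. Without standard replicate 3 the calls of FAP1, AKN2, ELF4 and DFR also ended.

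Dehydration of lyrata-labelled plants for 1 hour raised genes of the abscisic acid and drought response. NCED3, which encodes the enzyme that commits carotenoids to abscisic acid synthesis (chromosome 3, 4831286 to 4834015), rose from 1.38 ± 1.42 to 113 ± 141, a log2 fold change of 4.19 ± 0.78. DREB2A, a drought-responsive transcription factor (chromosome 5, 1602205 to 1604112), was listed at 0 in all 3 standard plants and at 99.2 ± 95.4 after dehydration (adjusted p = 0.017). RD29A, a target of such factors, rose by 3.62 ± 0.77. MLP328, of the major latex protein family, rose by 6.42 ± 0.95, and A/N-InvC by 4.29 ± 0.72. The falls included AT5G49700 (-3.76), EGY2 (-3.66), SETH3 (-3.42), AT3G20920 (-3.32) and AT5G03120 (-3.01).

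By list, 3 of 30 abscisic acid and dehydration genes rose in the dehydrated lyrata-labelled plants and 9 rose when adjusted over the list alone. In all, 29 of the 30 had a positive fold change, and camera called the list higher (adjusted p = 7.8e-08; adjusted p = 0.083 with an estimated correlation). None of 13 early cold regulators passed and 7 rose when adjusted over the list alone (camera adjusted p = 1.7e-06; adjusted p = 0.083 with an estimated correlation). Of 4 cold-regulated target genes, RD29A rose, and 2 rose when adjusted over the list alone (camera adjusted p = 0.012; adjusted p = 0.083 with an estimated correlation). The clock genes PRR5 (3.4 ± 0.56), PRR9 (2.67 ± 0.53) and LUX (2.91 ± 0.61) rose, and 7 of 23 rose when adjusted over the list alone (camera adjusted p = 0.027; adjusted p = 0.23 with an estimated correlation). None of 12 jasmonate genes passed and 4 rose when adjusted over the list alone (camera adjusted p = 0.00011; adjusted p = 0.23 with an estimated correlation). None of 15 touch, wound and defence genes passed and 5 rose when adjusted over the list alone (camera adjusted p = 4.9e-05; adjusted p = 0.23 with an estimated correlation). HSFB2A was the called gene among 9 heat shock genes (3.36 ± 0.67), with 1 when adjusted over the list alone.

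In all, limma called 55 of 13058 genes in the dehydrated lyrata-labelled plants (42 higher, 13 lower), and 2410 had an unadjusted p under 0.05. It called 0 without dehydration replicate 1 or standard replicate 3, 6 without dehydration replicate 2 (2 higher, 4 lower), 13 without standard replicate 1 and 335 without dehydration replicate 3. It called 0 when only the 6 libraries compared were fitted, 432 with library weights and 26 without the libraries that stood apart. With 10 added before log2 it called 53 higher and 26 lower, and with no filter 53 higher and 21 lower. Each of the 16 called genes named by the rule lost its call without at least dehydration replicate 1 and standard replicate 3, with an adjusted p of up to 0.24.

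In halleri-labelled plants, cold raised AT3G02480, annotated as a late embryogenesis abundant family gene (chromosome 3, 512220 to 513036), which was listed at 0 in all 3 standard plants and at 315 ± 154 in cold (adjusted p = 4.6e-05). PRR5 rose from 2.11 ± 2.29 to 126 ± 15.2, a log2 fold change of 5.12 ± 0.56, and LUX rose by 4.16 ± 0.61. AT4G05070 (4.68) and AT3G58550 (4.67) also rose, and MES18 was listed at 0 in the standard plants and at 50.5 ± 22 in cold. AT5G44568 was listed at 0 in the 3 cold plants and at 96.8 ± 103 in the standard plants (adjusted p = 0.0069). The other large falls were MIOX4 (-3.8), AT3G09440 (-3.7), CEF (-3.61) and AT4G37520 (-3.51).

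By list, PRR5, LUX and ELF4 rose among 23 clock genes in the cold halleri-labelled plants, and 5 rose and 1 fell when adjusted over the list alone; camera did not call the list (adjusted p = 0.14). ABF1, a transcription factor of abscisic acid signalling, rose (3.29) as 1 of 30 genes of that list, where 2 rose when adjusted over the list alone (camera adjusted p = 0.019; adjusted p = 0.4 with an estimated correlation). OPR3, of jasmonate synthesis, rose (4.02) as 1 of 12 jasmonate genes, with 1 when adjusted over the list alone (camera adjusted p = 0.0084; adjusted p = 0.4 with an estimated correlation). No early cold regulator of 13 passed and 5 rose when adjusted over the list alone (camera adjusted p = 0.001; adjusted p = 0.4 with an estimated correlation). ERF6 rose (3.51) among 15 touch, wound and defence genes, where 2 rose and 1 fell when adjusted over the list alone. PIP2;1 rose (2.65 ± 0.51) among 12 aquaporins, with 1 when adjusted over the list alone. None of 25 photosynthesis genes passed, and camera did not call that list (adjusted p = 0.54).

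Across 13058 genes, limma called 98 in the cold halleri-labelled plants (71 higher, 27 lower), and 1825 had an unadjusted p under 0.05. The count was 31 and 39 without cold replicates 2 and 3, 444 without standard replicate 1, and 24 and 25 without standard replicates 2 and 3. It was 2 when only the 6 libraries compared were fitted, 439 with library weights and 192 without the libraries that stood apart. Of the 16 called genes named by the rule, AT3G02480, PRR5, AT5G44568 and LUX kept their calls without any 1 library. The other 12 lost them without at least 1 library, with an adjusted p of up to 0.19. Cold replicate 1, without which 136 genes were called (76 higher, 60 lower), ended the calls of AT3G58550, OPR3 and ELF4 when left out.

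Dehydration of halleri-labelled plants gave the highest count of called genes of the treatments. ORA47, an activator of jasmonate synthesis, was listed at 0 in the standard plants and at 550 ± 717 after dehydration (adjusted p = 0.0028). RRTF1 was likewise listed at 0 and at 209 ± 152. ERF4 rose by 6.58 ± 0.92, to 594 ± 143 after dehydration, ERF8 rose by 6.77 ± 0.79, and DIC2, a mitochondrial dicarboxylate carrier gene, by 6.42 ± 1.04. NCED3 was listed at 0 in the standard plants and at 138 ± 41.2 after dehydration (adjusted p = 0.00053). The falls with the same limits on level and overlap included AT3G13930 (-5.42 ± 0.69), AT4G30170 (-5.15), KTI1 (-4.96 ± 0.99), CML11 (-4.94 ± 0.91) and MIOX2 (-4.74 ± 0.88).

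By list, 8 of 30 abscisic acid and dehydration genes rose in the dehydrated halleri-labelled plants, among them DREB2A (4.09 ± 0.84), ABF1 (2.99) and the phosphatase gene PP2CA (2.81 ± 0.57), and 15 rose when adjusted over the list alone (camera adjusted p = 1.6e-06; adjusted p = 0.13 with an estimated correlation). Of 13 early cold regulators 5 rose, among them ZAT10 (4.79 ± 0.86), CBF2 (4.53 ± 0.85) and HSFC1 (4.33), and 7 rose when adjusted over the list alone (camera adjusted p = 1.6e-06; adjusted p = 0.11 with an estimated correlation). Of 4 cold-regulated targets 3 rose, which were RD29A (2.88), RCI2A (3.02) and COR15B (3.54), also 3 when adjusted over the list alone (camera adjusted p = 0.001; adjusted p = 0.053 with an estimated correlation). Of 12 jasmonate genes 3 rose, which were OPR3 (5.65 ± 0.85), MYC2 (4.31 ± 0.99) and CYP94B3 (2.91), and 5 when adjusted over the list alone (camera adjusted p = 0.00016; adjusted p = 0.29 with an estimated correlation). Of 15 touch, wound and defence genes 5 rose, among them ERF6 (4.41), SZF1 (3.85) and TCH2 (3.15), and 6 when adjusted over the list alone (camera adjusted p = 0.00016; adjusted p = 0.32 with an estimated correlation). Of 23 clock genes 4 rose, among them PRR5 (5.37 ± 0.56), ELF4 (2.63) and LUX (2.33), and 8 when adjusted over the list alone (camera adjusted p = 0.022; adjusted p = 0.29 with an estimated correlation). LHCA2 rose (1.97) as 1 of 25 photosynthesis genes, with 5 when adjusted over the list alone (camera adjusted p = 0.022; adjusted p = 0.48 with an estimated correlation).

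Single called members of other lists in the dehydrated halleri-labelled plants were HSFB2A (2.89), the anthocyanin regulator PAP1 (2.91) and CYP79B2 of indole glucosinolate synthesis (3.24), each also the 1 rise of its list when adjusted over the list alone. Of the 9 heat shock genes 1 also fell when adjusted over the list alone, and 6 had a negative fold change (list median -0.3). SEP3, a floral organ gene, fell by 3.0 ± 0.65, from 21.5 ± 11.4 to 0.716 ± 0.62. TIP41L, a gene often used as a reference, rose by 2.56 ± 0.59, and it was also higher with the scaling as deposited (2.48) and with relative log expression scaling (2.61).

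Of 13058 genes, limma called 388 in the dehydrated halleri-labelled plants (269 higher, 119 lower), and 2498 had an unadjusted p under 0.05. The count was 166, 107 and 175 without dehydration replicates 1, 2 and 3, and 927, 131 and 106 without standard replicates 1, 2 and 3. It was 136 when only the 6 libraries compared were fitted, 1122 with library weights and 573 without the libraries that stood apart (378 higher, 195 lower). Of the 37 called genes named by the rule, 14 kept their calls without any 1 library, which were ORA47, ERF8, ERF4, RRTF1, DIC2, AT3G13930, CML11, MIOX2, ZAT10, CBF2, NCED3, OPR3, ERF6 and PRR5. The other 23 lost them without at least 1 of the 6 libraries, with an adjusted p of up to 0.21.

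**Figure D2:**
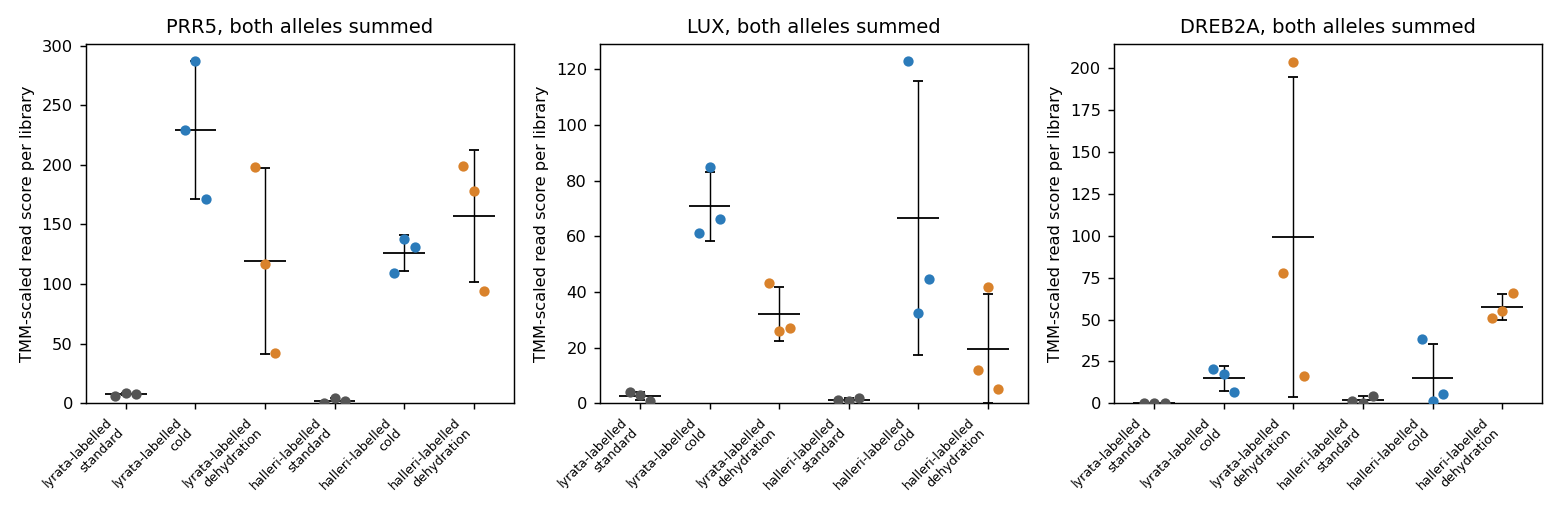
TMM-scaled values of PRR5, LUX and DREB2A, both alleles summed, for each plant (points), with the mean (line) and SD (bar) of each group of 3 plants. PRR5 lies at 7.69 ± 1.06 and 2.11 ± 2.29 in the standard groups and at 119 ± 77.7 to 229 ± 58 in the treated groups.

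**Figure D3:**
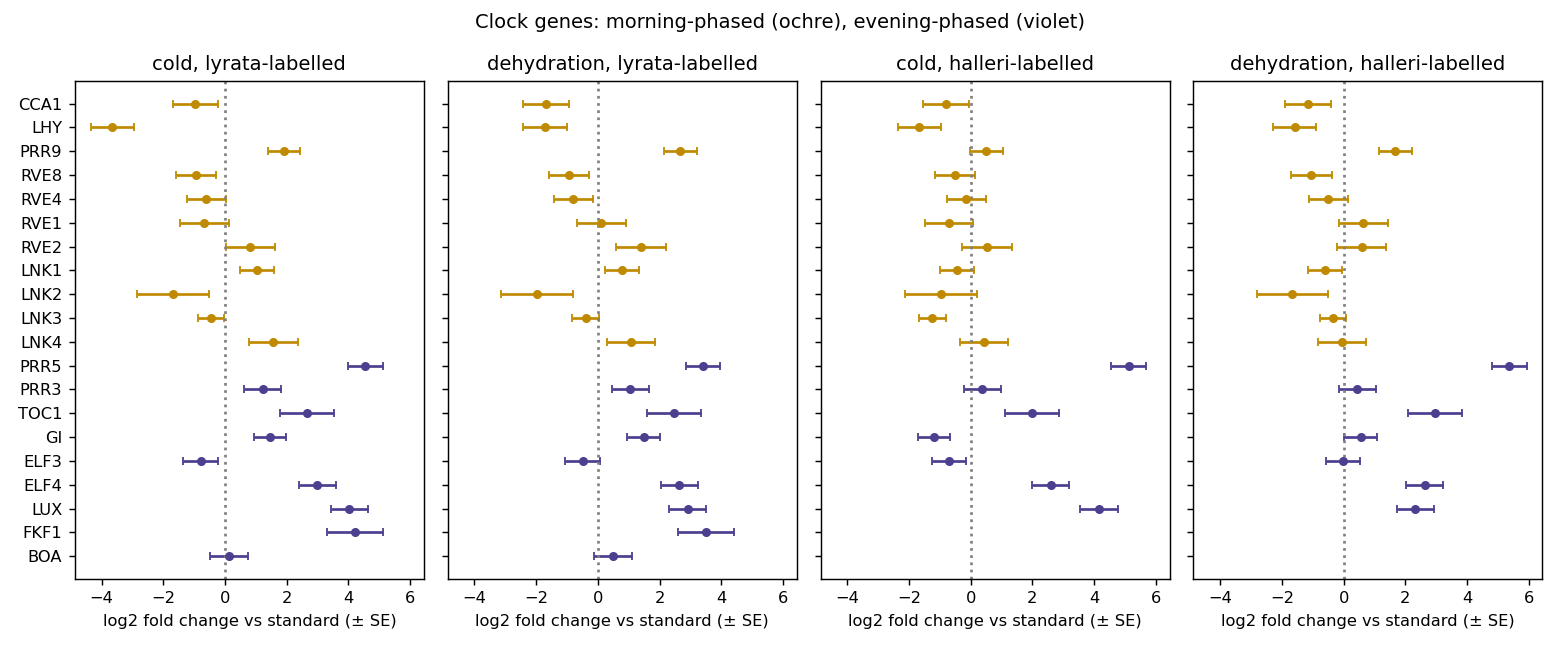
Log2 fold change of 20 clock genes against standard plants, with its SE (bar), in the 4 treatment comparisons, morning-phased genes in ochre and evening-phased genes in violet. FKF1 and BOA are left out of the halleri-labelled panels because they were listed at 0 in the standard plants there; PRR5 lies at 3.4 or above in all 4 panels.

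The treatment responses of the hybrids were then compared. They shared no control plants, but both came from 1 fit with 1 spread per gene. A gene of small spread is thus more easily called in both hybrids. Independent lists are therefore not an exact baseline, and the p values of Fisher's exact test below can overstate the agreement. Across the 13058 genes the log2 fold changes in cold correlated with r = 0.31 and rho = 0.28, and those in dehydration with r = 0.37 and rho = 0.35; genes are not independent replicates. In cold, 21 genes were called in both hybrids, all in the same direction (15 higher, 6 lower), where independent lists would share 0.45 higher and 0.066 lower genes (Fisher's exact test, 2-sided, p = 7.5e-24). In dehydration, 19 were called in both (18 higher, 1 lower), against 0.87 and 0.12 for independent lists (Fisher's exact test, p = 6.6e-16). A difference in sampling time or tissue between standard and treated plants, if common to both hybrids, would also give shared calls.

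PIP2;1, a plasma membrane aquaporin gene (chromosome 3, 19803473 to 19805730), differed between the hybrids in its response to cold. It was at 2250 ± 607 in standard and 566 ± 49.4 in cold in lyrata-labelled plants, and at 463 ± 266 and 3040 ± 1640 in halleri-labelled plants. The difference of the log2 fold changes was 4.6 ± 0.72 (adjusted p = 0.02). AT3G02480 was at 8.21 ± 7.36 and 11.3 ± 11.8 in lyrata-labelled plants, and listed at 0 and at 315 ± 154 in halleri-labelled plants (adjusted p = 0.02). These were the 2 genes limma called for a difference in cold response, of 1012 with an unadjusted p under 0.05. None of 25 photosynthesis genes passed in this test and 2 were higher when adjusted over the list alone. The list was higher by camera (adjusted p = 2.1e-05, and 0.3 with an estimated correlation), that is, its response to cold was shifted upward in halleri-labelled relative to lyrata-labelled plants. The aquaporins had 1 called gene and 3 when adjusted over the list alone (camera adjusted p = 0.00011; adjusted p = 0.3 with an estimated correlation). The photosynthesis and aquaporin lists were also higher by camera in the difference of the dehydration responses, with no gene called over all genes, 1 and 2 when adjusted over the list alone, and adjusted p = 0.0025 and 0.009 (both adjusted p = 0.43 with an estimated correlation). Both lists were lower in halleri-labelled than in lyrata-labelled standard plants (list median -1.2 for each). Those standard plants enter both differences, so the shifts are not independent of the standard levels.

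No gene was called by limma for a difference in dehydration response, of 1279 with an unadjusted p under 0.05, so the counts of 55 and 388 called genes do not show that the responses differ. Without halleri-labelled standard replicate 1, limma called 142 genes for the cold difference and 141 for the dehydration difference. For the cold difference it called 1 without lyrata-labelled cold replicate 1 or standard replicate 3, and 0 without lyrata-labelled cold replicate 2 or 3 or standard replicate 1, or without halleri-labelled cold replicate 2 or 3 or standard replicate 2. AT3G02480 and PIP2;1 lost their calls, with an adjusted p of up to 0.12, without 6 and 9 of the 12 libraries in turn. For PIP2;1 the 9 included lyrata-labelled standard replicate 3 and halleri-labelled standard replicate 3, without which 1 and 2 genes were called. When only the 12 libraries compared were fitted, limma called 0 genes for the cold difference (adjusted p = 0.091 for both). With a replicate block it also called 0. Without the libraries that stood apart the call of AT3G02480 ended (adjusted p = 0.16) and that of PIP2;1 did not (adjusted p = 0.0058). For the dehydration difference limma called 1 without lyrata-labelled dehydration replicate 2 and 2 without halleri-labelled dehydration replicate 3. With library weights the counts were 26 and 12.

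Under standard conditions the halleri-labelled plants were compared with the lyrata-labelled plants, in total expression of both alleles. PORA, a protochlorophyllide reductase gene (chromosome 5, 21990864 to 21992814), was at 1160 ± 1110 in halleri-labelled and 16.7 ± 9 in lyrata-labelled plants (5.66 ± 0.75). MLP328 was higher by 4.98 ± 0.95, and ALDH6B2 (4.66) and AT3G55840 (4.59) were also higher. AT3G15070 was listed at 0 in the lyrata-labelled standard plants and at 51.9 ± 12.8 in the halleri-labelled plants. AT2G29150 (-5.87 ± 0.6) and the expansin gene EXPA5 (-5.25 ± 0.74) were lower in halleri-labelled plants. AT2G25150, AT1G10400 and the auxin influx carrier gene LAX1 were listed at 0 in halleri-labelled standard plants and at 254 ± 152, 181 ± 208 and 110 ± 113 in lyrata-labelled plants.

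Of 24 metal homeostasis genes, 3 were lower in halleri-labelled plants, which were IRT3 (-3.66 ± 0.6), MTP1, a vacuolar zinc transporter gene (-3.84 ± 0.71), and ZIP6 (-2.39 ± 0.61). MTP3 was higher (3.29 ± 0.65). With the p adjusted over the list alone, 6 were lower and 1 higher, and camera called the list lower (adjusted p = 0.0032; adjusted p = 0.051 with an estimated correlation). Of 12 aquaporins, PIP2;7 (-2.82 ± 0.48) and PIP2;1 (-2.38 ± 0.51) were lower, and 5 when adjusted over the list alone (camera adjusted p = 0.00059; adjusted p = 0.21 with an estimated correlation). Of 25 photosynthesis genes, LHCB4.2 was lower (-2.49 ± 0.49), and 6 when adjusted over the list alone (camera adjusted p = 0.0038; adjusted p = 0.71 with an estimated correlation). CHE of the clock list (-2.82 ± 0.55) and DRM2 of the dark and starvation list (-5.08) were lower, as 1 gene of each list, with 2 and 1 lower when adjusted over the list alone.

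Between the hybrids under standard conditions, limma called 253 of 13058 genes (67 higher and 186 lower in halleri-labelled plants), and 2286 had an unadjusted p under 0.05. The count was 76 without lyrata-labelled standard replicate 1, and 607, 104 and 78 without halleri-labelled standard replicates 1, 2 and 3. It was 12 when only the 6 libraries compared were fitted, 466 with library weights and 77 without the libraries that stood apart. Of the 19 called genes named by the rule, PORA, MLP328, AT2G25150, AT1G10400, AT2G29150, LAX1, EXPA5, PIP2;7 and IRT3 kept their calls without any 1 library. The other 10 lost them without at least 1, with an adjusted p of up to 0.17; MTP1 did so without lyrata-labelled standard replicate 1 and MTP3 without halleri-labelled standard replicate 3. Lyrata-labelled standard replicates 2 and 3, without which 191 and 202 genes were called, also ended the calls of ALDH6B2, DRM2 and ZIP6 when left out, and replicate 2 that of AT3G55840.

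The alleles were compared within each plant. In lyrata-labelled plants the non-thaliana allele prevailed at the cytochrome P450 gene CYP709B2 (chromosome 2, 19289087 to 19291632), with a log2 ratio of 7.04 ± 0.18. It also prevailed at AT3G28500 (6.64), BG3 (6.26), AT2G29150 (5.92) and AT1G24735 (5.76). The thaliana allele prevailed at BCB, a copper-binding protein gene (-6.0 ± 0.46), AT4G18440 (-5.06), AT3G24080 (-4.99), AT4G32590 (-4.97) and AT2G38450 (-4.8). A ratio includes any difference in how well reads of each allele could be assigned, which parental or genomic reads would be needed to measure.

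Metal homeostasis genes stood out among the lists in lyrata-labelled plants. MTP1 (chromosome 2, 19235374 to 19239577) had a non-thaliana to thaliana ratio of 10.4 (adjusted p = 7e-09), ZIP6 of 10.1, ZIP3 of 8.85, NRAMP3 of 8.69, IRT3 of 7.2, and HMA4, a zinc and cadmium pump gene (chromosome 2, 8278789 to 8286561), of 5.31 (adjusted p = 2.2e-06). In all 9 plants the non-thaliana allele of HMA4 was the higher. Of 21 measured metal genes, 13 favoured the non-thaliana allele and 1 the thaliana allele, or 14 and 1 when adjusted over the list alone. Camera called the list (adjusted p = 4.5e-05; adjusted p = 0.54 with an estimated correlation), and Fisher's exact test of the directions against all other called genes gave an adjusted p of 0.01. In halleri-labelled plants the same test gave 9 and 3 of 18 genes, also when adjusted over the list alone, and camera did not call the list (adjusted p = 0.69). There HMA4 had a ratio of 1 (adjusted p = 0.98), MTP1 of 1.49 (adjusted p = 0.00011), ZIP11 of 1.98 and MTP3 of 13.5 (adjusted p = 2.7e-07), the last 3 with the non-thaliana allele higher in all 9 plants. In lyrata-labelled plants MTP3 was too low to be tested, at 5.33 ± 7.23 for the non-thaliana and 3.78 ± 3.38 for the thaliana allele.

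**Figure D4:**
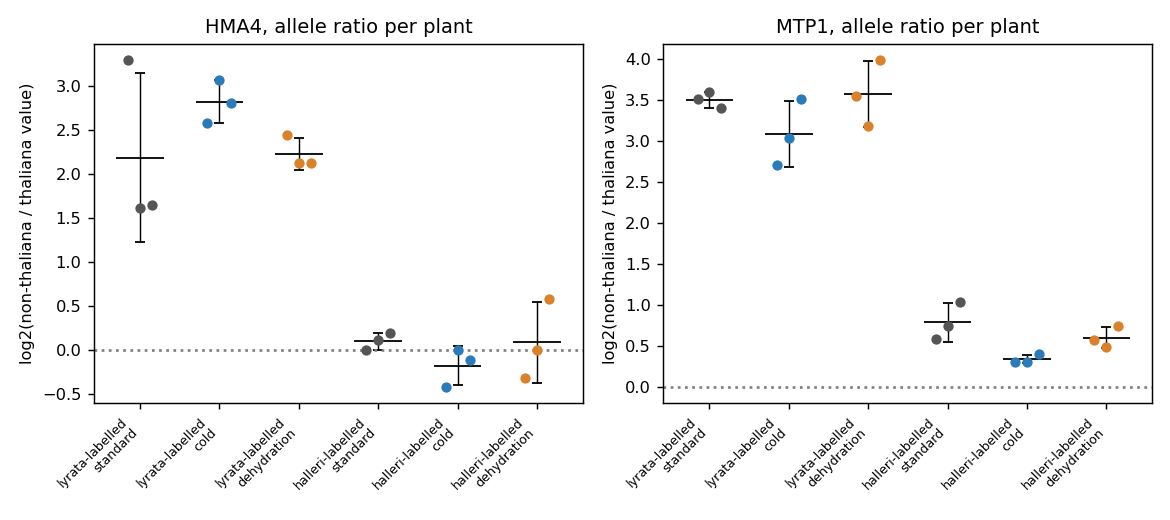
Log2 ratio of non-thaliana to thaliana allele at HMA4 and MTP1 for each plant (points), with the mean (line) and SD (bar) of each group of 3 plants; the dotted line marks equal alleles. All 9 lyrata-labelled plants lie above every halleri-labelled plant at both genes.

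Genes of the stress lists favoured both alleles in lyrata-labelled plants. Of 26 abscisic acid and dehydration genes, 11 favoured the non-thaliana allele, among them RD20 (1.95) and RD29A (2.48), and 3 the thaliana allele, among them P5CS1, of proline synthesis (-3.43 ± 0.26); the counts were 11 and 3 when adjusted over the list alone. Of 13 early cold regulators 3 favoured each allele, CBF2 the thaliana allele (-2.6). Of 22 clock genes 7 favoured the non-thaliana and 3 the thaliana allele, LUX among the latter (-1.93). CYP79F2 of aliphatic glucosinolate synthesis (2.94) was the 1 of 11 glucosinolate genes toward the non-thaliana allele, against 5 toward the other, and VSP2 (2.2) was among 5 of 11 jasmonate genes, against 4. These counts did not differ when adjusted over the list alone. Camera called no other list in lyrata-labelled plants. By fry, which does not compare a list with other genes, the ratios lay on balance toward the non-thaliana allele for the metal (adjusted p = 3.4e-05), reference (3.4e-05), cold-regulated target (0.001) and abscisic acid (0.02) lists, and toward the thaliana allele for the aquaporins (0.00096). In all, limma called 5409 of 11697 genes (2567 toward the non-thaliana and 2842 toward the thaliana allele), and 1689 of them differed by over 2-fold (894 and 795). The side with more calls depended on the setting: the counts were 3055 and 2522 without dehydration replicate 2, 2894 and 2527 without the libraries that stood apart, 2997 and 2809 with library weights, and 3165 and 3117 with no filter. The median absolute log2 ratio was 0.4. With a mean of at least 50 required the count was 2734, since fewer genes were tested.

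In halleri-labelled plants the largest ratio was at PORA, where the non-thaliana allele led by 8.48 ± 0.19 on the log2 scale (adjusted p = 1.7e-09). DIN11 (5.43), GSTU15 (5.32), MLP328 (5.19 ± 0.23) and NLM1 (5.06) also had high ratios. The thaliana allele led at LRR XI-23 (-6.13 ± 0.2), AT3G18680 (-6.06), AT1G63290 (-5.19), the arginase gene ARGAH2 (-4.63 ± 0.13) and AT3G23570 (-4.53). Among 25 abscisic acid and dehydration genes, 14 favoured the non-thaliana allele, among them CYP707A2 (3.07), RD20 (3.02) and PP2CA (1.5), and 8 the thaliana allele, or 15 and 8 when adjusted over the list alone. ERF2 (-3.39) favoured the thaliana allele among 15 touch, wound and defence genes, which split 5 and 5 (non-thaliana, then thaliana), and LOX2 (-2.75) among 11 jasmonate genes, which split 2 and 4. MBF1C (-2.48) did so among 8 heat shock genes (1 and 3) and TIP2;1 (-2.24) among 12 aquaporins (6 and 4). Of 22 clock genes 7 favoured the non-thaliana allele, among them LNK3 (1.32), and 6 the thaliana allele, among them LUX (-1.83). F3H (1.65) was among 4 of 8 flavonoid genes toward the non-thaliana allele, against 0. These splits were equal when adjusted over the list alone. Camera called none of the lists in halleri-labelled plants, and fry called 10. In all, limma called 6894 of 11655 genes (3986 toward the non-thaliana and 2908 toward the thaliana allele), 1873 of them by over 2-fold (1184 and 689). With the ratio of most genes centred at 0 the larger side turned, at 3338 and 3575 (48.3% toward the non-thaliana allele in place of 57.8%). With a mean of at least 50 required it called 3615, since fewer genes were tested. Across 11193 genes measured in both hybrids the log2 ratios correlated with r = 0.59 and rho = 0.56. Of 3528 genes called in both, 3158 favoured the same side; the thaliana parent was Col-0 in both hybrids by the labels.

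Changes of the allele ratio with treatment were few in lyrata-labelled plants. At AT5G02240 (chromosome 5, 451406 to 453496), annotated as a Rossmann-fold protein, the log2 ratio fell from -1.42 ± 0.63 (SD, n = 3) in standard to -6.64 ± 0.26 in cold and -6.3 ± 0.47 in dehydration. At COR15B, a cold-regulated chloroplast protein gene (chromosome 2, 17708593 to 17710433), it fell from 3.0 ± 0.61 to 0.4 ± 0.34 in cold and -0.36 ± 0.24 in dehydration. CRR6 (-2.67 in cold, -2.12 in dehydration) moved toward the thaliana allele in both treatments, and AT4G08280 (2.07 and 1.93) toward the non-thaliana allele. PFD6 (-2.64) changed in cold, and HSFC1 (-2.3), AT1G11930 (-2.24) and Fes1B (-2.19) changed in dehydration. COR15B was the called gene among 4 cold-regulated targets in both treatments, with 1 in cold and 2 in dehydration when adjusted over the list alone. HSFC1 was the called gene among 13 early cold regulators in dehydration, where 4 fell when adjusted over the list alone. Where a gene was barely detected in standard plants, the 1 added to each allele holds its ratio near equality. A constant difference between the alleles can then appear as a change of ratio once the gene rises, in either hybrid. Apart from the setting with 0.5 added to each allele, this was not tested. Camera called no list, with adjusted p values of at least 0.2 in cold and 0.16 in dehydration.

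Among 11697 genes, limma called 15 for a change of ratio with cold (3 higher, 12 lower; 1194 with an unadjusted p under 0.05) and 11 with dehydration (1 higher, 10 lower; 1545). The median change of all genes with dehydration was -0.24. Without lyrata-labelled dehydration replicate 2 it was -0.02, with 2 genes called higher and 4 lower, so the median shift toward the thaliana allele rested on that plant. With the ratio of most genes centred at 0, the counts were 59 (24 higher, 35 lower) and 16 (5 higher, 11 lower). For cold the count was 5, 8 and 4 without cold replicates 1, 2 and 3, 52 without dehydration replicate 2, and 6 and 9 without standard replicates 1 and 2. For dehydration it was 6 without any 1 of cold replicates 1, 2 and 3, 5, 6 and 30 without dehydration replicates 1, 2 and 3, and 3 without any 1 of the standard replicates. With library weights the counts were 103 and 5, and 8 and 3 without the libraries that stood apart, where the larger side turned (5 higher and 3 lower with cold, 2 higher and 1 lower with dehydration). Of the genes called without those libraries, 3 (cold) and 1 (dehydration) were also called in the main fit. At most 1 of AT5G02240 and COR15B thus kept its dehydration call there. AT5G02240 kept both of its calls and PFD6 its cold call without any 1 plant. COR15B likewise kept its dehydration call when 1 plant was left out, and lost its cold call without any 1 of cold replicates 1 to 3 or standard replicates 1 and 2 (adjusted p of up to 0.11). The other named calls ended without at least 1 plant, with an adjusted p of up to 0.2; those of CRR6 and AT4G08280 in cold did so without cold replicate 3.

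In halleri-labelled plants more changes of ratio were called, and the difference from lyrata-labelled plants was not tested. At AT1G21930 (chromosome 1, 7712819 to 7714459) the log2 ratio was -4.48 ± 0.68 in standard, 0.63 ± 0.13 in cold and 0.54 ± 0.21 in dehydration. At AT2G03390 (chromosome 2, 1030402 to 1032718) it was -4.79 ± 0.92, 0.65 ± 0.14 and -0.39 ± 0.3. At FUM2, a cytosolic fumarase gene (chromosome 5, 20729431 to 20733941), it was 3.39 ± 0.68, 0.41 ± 0.72 and 0.66 ± 0.23. Further changes with cold were at NIT2 (5.36), AT3G28500 (4.1), SRS (3.48), AT1G58280 (-3.68), LHCB4.3 (-2.78), FLA13 (-2.61) and AT3G16220 (-2.56). Further changes with dehydration were at NIT2 (5.57), BGLU11 (4.45), SRS (3.57), BG3 (-3.98), CML11 (-3.4), XTH33 (-3.35) and AT1G50740 (-2.99).

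By list, the ratio at COR47 (-1.23) and RCI2A (-2.1) fell with cold in halleri-labelled plants, as 2 of 4 cold-regulated targets and also 2 when adjusted over the list alone. Of 25 abscisic acid and dehydration genes 2 rose, among them PP2CA (1.13), and 1 fell, or 3 and 1 when adjusted over the list alone. Of 25 photosynthesis genes 1 rose and 2 fell, among them PSBR (-1.27), but 7 rose and 3 fell when adjusted over the list alone. RVE2 rose (1.83) as 1 of 22 clock genes, with 1 when adjusted over the list alone, and TIP1;2 fell (-1.3) as 1 of 12 aquaporins, where 1 rose and 1 fell when adjusted over the list alone. With dehydration the ratio fell at HSFC1 (-1.51), 1 of 12 early cold regulators (1 rose and 2 fell when adjusted over the list alone), and at COR47 (-0.92), 1 of 4 cold-regulated targets (2 fell when adjusted over the list alone). Of 12 aquaporins 1 rose and 1 fell, the latter TIP1;2 (-1.38), or 2 and 2 when adjusted over the list alone. CYP94C1 (1.77) and JAZ2 (1.36) rose as 2 of 11 jasmonate genes, with 3 higher and 2 lower when adjusted over the list alone, and RVE2 (1.77) as 1 of 22 clock genes, with 1 and 1. Camera called no list, with adjusted p values of at least 0.15 in cold and 0.61 in dehydration.

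In all, limma called 295 of 11655 genes for a change of ratio with cold (133 higher, 162 lower) and 453 with dehydration (202 higher, 251 lower). The larger side turned for cold with the ratio of most genes centred at 0 (138 higher, 120 lower) and without cold replicate 1 (88 and 84), and for dehydration with library weights (208 and 204) and without standard replicate 1 (397 and 395). Both changes are taken against the same 3 standard plants, whose ratios correlated across genes with those of the treated plants with r between 0.615 and 0.708, against 0.758 to 0.813 between cold and dehydrated plants and 0.688 to 0.817 among the standard plants. A difference of the standard plants other than treatment, such as the tissue left open above, cannot be told apart from these changes. For cold the count was 172, 101 and 100 without cold replicates 1, 2 and 3, 195 without dehydration replicate 3, and 559 and 158 without standard replicates 1 and 3. For dehydration it was 276 without cold replicate 3, 191, 154 and 144 without dehydration replicates 1, 2 and 3, and 792, 297 and 226 without standard replicates 1, 2 and 3. For cold it was also 491 with library weights and 172 without halleri-labelled cold replicate 1, the library of this hybrid that stood apart. Of the genes named here, AT1G21930, AT2G03390, FUM2 and TIP1;2 kept both calls without any 1 plant. For cold so did AT1G58280, LHCB4.3, FLA13, COR47, PP2CA and PSBR, and for dehydration CML11, XTH33 and AT1G50740. The other named calls ended without at least 1 plant, with an adjusted p of up to 0.17 in cold and 0.13 in dehydration.

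Markers of other tissues and reference genes were read in the same tests. None of 3 measured root markers was called in any treatment response or between the hybrids under standard conditions, and 1 was lower in cold lyrata-labelled plants when adjusted over the list alone. SEP3 was the floral organ gene measured, and it was called in dehydrated halleri-labelled plants as given above. When adjusted over the list alone, which is this gene, it was also lower in dehydrated lyrata-labelled and cold halleri-labelled plants, and higher in halleri-labelled than in lyrata-labelled standard plants. Of 3 measured reference genes, TIP41L was called in that comparison alone among the treatment responses, and 1 reference gene was higher in cold and 1 in dehydrated halleri-labelled plants when adjusted over the list alone. None of 8 auxin and growth genes was called over all genes in any treatment response or between the hybrids. When adjusted over the list alone, 1 was higher and 3 were lower in halleri-labelled than in lyrata-labelled standard plants, 1 was higher and 1 lower in cold halleri-labelled plants, and none in the other treatment responses. The fry test for change in either direction gave adjusted p = 0.0014 and 0.0045 in those comparisons.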

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

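The tests of lyrata-labelled dehydration replicate 2 were chosen after the result was seen. The median ratio and the named allele ratios of each hybrid gave 22 sets of values tested for an outlying plant, and 4 had one. For normal, independent values chance gives about 1 in 20. These sets share plants, and most median ratios of halleri-labelled plants were exactly 0, so that rate is only a guide.

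Lyrata-labelled dehydration replicate 2 lay far from the other 8 lyrata-labelled plants, with a median log2 allele ratio of -0.709 against -0.064 to 0.08. Its shift against the other dehydration replicates was -0.66, -0.69, -0.66, -0.69 and -0.71 on chromosomes 1 to 5. The shift nearest 0 was -0.66, which argues against loss or gain of single chromosomes. Genes that rose in dehydrated halleri-labelled plants, which are other libraries, shifted less than genes that fell there (131 and 54 genes, medians -0.39 and -0.87). The difference was 0.48 ± 0.09 (SE from 1000 bootstrap draws of genes, which are not independent), against -0.13 to 0.13 in the other 8 lyrata-labelled plants. The ends of that range are dehydration replicates 1 and 3, each compared with the other alone, so they are 1 value with its sign turned. The cold and standard plants lay between -0.09 and 0.12. These values argue against an extra thaliana genome as the whole cause, since a gene dose alone would shift these genes alike. *A. thaliana* RNA of plants in another state mixed into the library (a shift of up to -0.71) may account for it, and no biological explanation that the design names was tested.

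The ratio at AT4G32590 was -2.49 in lyrata-labelled standard replicate 1, against -6.68 to -4.64 in the other lyrata-labelled plants. The median ratio of halleri-labelled standard replicate 1 was 0.074, against 0 to 0.015 in the other halleri-labelled plants. The ratio at NLM1 was 1.58 in halleri-labelled cold replicate 1, against 4 to 6.25 in the others.

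The cold response of AT3G02480 differed between the hybrids by 6.78 on the log2 scale in limma's interaction test (adjusted p = 0.02), a size that rests on the 2 added, as the halleri-labelled standard plants were listed at 0. That of PIP2;1 differed by 4.6 ± 0.72 (adjusted p = 0.02). AT3G02480 lost its call without 6 and PIP2;1 without 9 of the 12 libraries in turn, and both did when only the groups compared were fitted (adjusted p = 0.091). Both calls also ended with a replicate block. For this comparison 8 of 100 splits of the plants gave at least 2 genes, so chance cannot be excluded.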

How the results depend on the processing

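Alternatives chosen after the data were seen were the scaling as deposited, 10 added before log2, library weights and leaving out the libraries that stood apart. The DESeq2 alternatives were not run, because the deposited values are not counts. Of the values of named genes under all alternatives, 12961 kept direction and side of the threshold, and 768 lost and 213 gained a call. A further 142, of genes not called in the main fit, changed direction, and 0 of called genes did. Relative log expression scaling, no filter and the scaling as deposited left all 7 total counts within 1.5 times, but the scaling as deposited moved the median of all genes to 0.23 and 0.11 for cold and dehydration in lyrata-labelled plants, -0.18 and -0.16 for the differences between hybrids and 0.12 between hybrids in standard. The cause of the changes below was not tested, except that a mean of at least 50 tests fewer genes and fits of fewer libraries have fewer degrees of freedom.

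Same-numbered libraries did not deviate together (45 pairs, median r -0.019, -0.28 to 0.17, 2 above 0.1), and 5 of 18 libraries correlated best with their own number. With a replicate block limma called 75 genes for cold and 22 for dehydration in lyrata-labelled plants, 0 for the difference in cold response and 4 for the lyrata-labelled change of ratio with dehydration; no other count moved by over 1.5 times. With only the groups compared it called 12 and 0 (cold and dehydration, lyrata-labelled), 2 and 136 (halleri-labelled), 0 for the difference in cold response and 12 between hybrids in standard. With 10 added it called 1 for the difference in dehydration response. Library weights gave 520, 432, 439 and 1122 for these 4 responses, 26 and 12 for the differences, 466 in standard, 103 and 5 for the lyrata-labelled changes of ratio and 491 for the halleri-labelled change with cold. Without the libraries that stood apart the counts were 60, 26 and 192 (cold and dehydration lyrata-labelled, cold halleri-labelled), 1 for the difference in dehydration response, 77 in standard, 8 and 3 for the lyrata-labelled changes of ratio and 172 for the halleri-labelled change with cold. Centring gave 59 for the lyrata-labelled change with cold; for halleri-labelled plants it gave 48.3% of called ratios toward the non-thaliana allele in place of 57.8%. A mean of at least 50 gave 2734 and 3615 called ratios. Camera called 33 of 202 list tests, and 0 with an estimated correlation. Fry called 30, 14 of them shared with camera; 17 of the 30 were allele ratio tests, where camera called 1.

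Leaving out 1 library gave 22 to 80 genes for cold and 0 to 335 for dehydration in lyrata-labelled plants, and 24 to 444 and 106 to 927 in halleri-labelled plants. It gave 0 to 142 and 0 to 141 for the differences in cold and dehydration response and 76 to 607 in standard. The changes of ratio ranged from 4 to 52 with cold and 3 to 30 with dehydration in lyrata-labelled plants, and from 100 to 559 and 144 to 792 in halleri-labelled plants. Called ratios ranged from 4574 to 5577 and from 6226 to 6871. The highest counts of the halleri-labelled responses and changes came without standard replicate 1. Where 1 group was left with 2 plants, its spread was taken from all groups.

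A comparison of 3 against 3 plants has 10 splits, too few for a share under 0.05; in each, 1 of 10 splits, the real one, reached the real count. The real and the highest other counts were 115 and 0, 55 and 2 (cold and dehydration, lyrata-labelled), 98 and 11, 388 and 4 (halleri-labelled), 253 and 39 (standard), 15 and 0, 11 and 2 (changes, lyrata-labelled), and 295 and 1, 453 and 0 (changes, halleri-labelled). For allele ratios the alleles were instead exchanged within randomly chosen plants, and 1 of 100 arrangements, the real one, reached the real count. It was 5409 against at most 2335 (lyrata-labelled) and 6894 against at most 3199 (halleri-labelled). Such exchanges cancel any ratio that repeats between plants, so they show that ratios repeated. They cannot tell cis-regulation from a difference in how reads were assigned. For the difference in cold response 8 of 100 splits gave at least 2 genes, up to 8, so chance cannot be excluded. For dehydration the real count was 0, which every split reaches, so the splits decide nothing there. The highest other split called 199 genes, and its cause was not examined.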

Other observations

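The tests of the metal genes were chosen after the result was seen; those of the clock genes were written after PRR5 and the list counts had been seen but before their own results.

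Of 25 photosynthesis genes in halleri-labelled plants, 11 favoured the thaliana and 4 the non-thaliana allele, also when adjusted over the list alone, among them LHCB4.2 (-1.5). The split did not pass Fisher's exact test of the directions against the other called genes (adjusted p = 0.31) or camera (adjusted p = 0.46). In lyrata-labelled plants 5 favoured the thaliana and 3 the non-thaliana allele (5 and 2 when adjusted over the list alone). Flavonoid genes favoured the non-thaliana allele at 4 of 8 genes in halleri-labelled plants, among them F3H (1.65) and CHI (1.35), and at 0 of 8 in lyrata-labelled plants by limma (4 and 0 when adjusted over the list alone). Fisher's exact test of the directions in halleri-labelled plants gave an adjusted p of 0.72, and the difference between the hybrids was not tested. Camera called neither list in either hybrid. The ratios of lyrata-labelled plants correlated with each other, across genes, with r between 0.5 and 0.83 (median 0.63), the highest between cold replicate 1 and dehydration replicate 3. Those of halleri-labelled plants correlated with r between 0.61 and 0.91 (median 0.71). Within a treatment the median r was 0.68 (0.57 to 0.75) in lyrata-labelled and 0.83 (0.69 to 0.91) in halleri-labelled plants, where standard against treated plants gave 0.615 to 0.708.

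Evening-phased clock genes lay above morning-phased genes in all 4 treatment comparisons, with differences of medians of 3.24, 2.86, 2.48 and 2.83 (exact permutation over genes, p = 0.0028, 0.017, 0.0054 and 0.00075; cold and dehydration in lyrata-labelled, then in halleri-labelled plants). The lowest, 2.48, is a value that sampling treated plants at a later clock time than standard plants would give, so such a difference may contribute, and the labels do not state the times. The permutations treat genes as independent, and PRR5 had been seen. Whether each treatment also moved the clock in its own way cannot be told apart: cold against dehydration gave fry mixed p of 0.33 and 0.099, and the bound set for this test excludes nothing, since changes of up to 3.33 and 3.05 at single clock genes remain possible. Dim light, given in both treatments, and a response of the clock to stress stay open and untested, and the comparisons within a hybrid share their standard plants.

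The non-thaliana allele of HMA4 and MTP1 was higher in lyrata-labelled than in halleri-labelled plants, while MTP3 had its high non-thaliana ratio (13.5) in halleri-labelled plants; as background, *A. halleri* is the metal hyperaccumulator of the pair. A few plants do not carry the difference, as 9 of 9 lyrata-labelled plants lay above every halleri-labelled plant at HMA4 and MTP1. An exchange of the hybrids' labels and an exchange of the file headers alone cannot be told apart. The gaps at the 2 genes (1.03 and 1.67) are the pattern itself, the bound on the HMA4 log2 ratio of halleri-labelled plants (0.27) rests on an assumed profile of *A. halleri*, and MTP3 goes the other way. MTP3 was too low to be tested in lyrata-labelled plants, and other metal genes did not enter these tests. Over the metal list, 13 of 21 genes favoured the non-thaliana allele in lyrata-labelled plants (1 the thaliana allele). In halleri-labelled plants 9 of 18 did (3 the thaliana allele), and the difference between the hybrids was not tested. A difference between the parents as labelled stays open and was not tested.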
